A study of Danio rerio with 6 samples.

How the data were processed

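The series compared kdrl-positive endothelial cells with and without NF-kB reporter fluorescence, sorted from dissected trunks of zebrafish embryos at 22 hpf, with 3 libraries per sort and about 7000 cells per library. Per the labels' protocols, total RNA was extracted from the sorted cells and made into libraries with a low-input kit. The labels do not state whether strand was kept, so reads of overlapping antisense genes cannot be separated. They call the samples biological replicates, and whether each came from a separate pool of embryos is not stated. If not, the p-values measure only the spread between these samples.

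The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq2 and the genome build danRer10, with no versions, roles or order. The annotation is not given in the sources used here. Per the file headers, the authors deposited 1 table of 2475 rows, with a log2 value for each of the 6 libraries, a signed fold change, a log2 fold change, a p-value and an adjusted p-value per gene, and an average log2 expression. The authors' log2 values per library were checked against the numbers themselves. Taking 2 to the power of a value and subtracting 1 gave whole multiples of 1 step per library, within 0.1 read, for 100% of the values under 1000 reads in each library. The values are thus log2 of reads divided by a size factor, plus 1. The recovered size factors were 0.963, 0.834 and 1.56 for the NFKB+ libraries and 0.886, 1.04 and 0.918 for the NFKB- libraries. The authors' average log2 expression equalled the log2 of the mean of these normalized reads within 8.52e-05. The authors' log2 fold change was smaller than the difference of the libraries' means for low genes, with a median size of 2.04 against 2.77 for the 115 genes under a mean of 50 normalized reads. The authors' signed fold score is 2 to the power of that log2 fold change, with a minus sign for a fall, per the file headers and values. An adjusted p-value was written as 0 by the authors for 496 genes.

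The deposited table had been filtered on the outcome. Every analysed gene met 2-fold and adjusted p 0.01 in the authors' table. The genes mafba and efna2a had 2 rows each, with the same library values in both and high and low values alternating between columns. Reading columns 1, 3 and 5 as the NFKB+ libraries of the higher row gave back the deposited average within 0.00196 for mafba and 0.00499 for efna2a. Their 4 rows were left out, and 2 of these were the table's exceptions to the authors' limits. This left 2471 genes, with means from 6.89 normalized reads upwards and a median of 1002. In 3 rows the gene name had been turned into a date, and these genes were not named. Genes that did not pass the authors' limits were not analysed here, so counts describe a selected list, and library depth, total numbers of changed genes and enrichment against unchanged genes could not be computed.

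The columns carry the sort and a number from 1 to 6 that runs over both sorts. They were therefore assigned to a sort and not to a single labelled replicate, and libraries are named here by those column numbers. Pairs of libraries within a sort differed by more than sampling noise, with a chi-square per degree of freedom between 24.7 and 113, so no library looked like a copy of another. This does not show that they came from separate pools, and each was counted as a replicate because the labels call it one. The reads in the table ranged from 8393821 to 15165088 per library. At the median gene, about 1002 normalized reads, counting error is small beside the spread between libraries. Genes with few reads, such as itga2b and runx1, are less precise.

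The sorts were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend) on log2(normalized reads + 1), with a pseudocount of 1, no low-value filter and no covariate. P-values were adjusted with the Benjamini-Hochberg method over the 2471 genes at a threshold of 0.05. Differences are NFKB+ minus NFKB-, and folds are 2 to the power of their size. They are ratios of geometric means of normalized reads plus 1, so for low or variable genes they can differ either way from the ratio of mean reads. For itga2b, with a 10.7-fold difference, the mean normalized reads were 10.1 in NFKB+ and 70.5 in NFKB- libraries. Because the table holds log values, limma was used and no count test was run on it as the main result. The step was tested on simulated counts for the 2471 genes of this comparison, with a dispersion of 0.01385 and 200 changed genes. It recovered 96 of 100 genes changed by 1 and 100 of 100 changed by 2 on the log2 scale, and 9 of its 205 calls (4.39%) were false. Most simulated genes were unchanged and all had the same dispersion, unlike the selected genes analysed, so these shares do not carry over to them.

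The 25 gene lists, the rule for named genes and the alternative settings, save those named below as added, were fixed before the data were examined. They were lists of NF-kB pathway, inflammatory, pan-endothelial, arterial and Notch, venous and lymphatic, hemogenic and progenitor, erythroid, myeloid, muscle, neural, notochord, epidermis, pronephros, neural crest, fibroblast, G1/S, G2/M, cell cycle inhibitor, apoptosis, BMP and TGF-beta, Wnt and Hedgehog, flow and junction, stress, ribosomal protein and mitochondrial genes. Members were matched by symbol or through NCBI gene IDs. Of the IDs, 2444 (98.9%) matched the reference gene table of assembly GRCz12tu. It was used for names alone and no coordinates are given, because the authors' build differs. For the 15 lists with at least 5 analysed members, a two-sided Fisher's exact test in scipy 1.17.1 compared higher and lower genes between the list and the remaining genes of the table, with Benjamini-Hochberg adjustment over the 15 lists. On simulated lists of 20 genes, 3.4% of 500 draws at the table's own share of higher genes and 99.2% of 500 draws at 95% higher gave p under 0.05. The real lists that did not pass held at most 20 members and were less one-sided, and their p-values were adjusted. The 99.2% therefore does not carry over to them.

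Named genes were the 10 largest positive and 10 largest negative log2 differences among genes past the threshold with non-overlapping groups, a mean at or above the table's median and a symbol that is not a clone or locus name. To these came up to 4 members of each list by size of difference (up to 6 for the NF-kB, hemogenic, arterial and cell cycle lists). The genes kdrl, runx1, gata2b, myb, nfkbiaa, rela, cdkn1a and ccnd1 were also fixed by name, of which kdrl, runx1, myb and ccnd1 were analysed. Members named to complete a count of 5 or fewer (lmo4a, fli1a, zeb2a, fzd9b, rspo3, hsp90aa1.2, dusp2, hspa4a, egr2b, egr3) and genes named in the closing section outside the rule were chosen after their values were seen. Globins and keratins are families of near-identical copies whose reads may be shared.

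Alternatives changed the pseudocount (0.5 or 10), a minimum mean (10 or 100), the scaling (same total over the table, or median ratios over the table), the eBayes trend, library weights, the threshold (adjusted p 0.01, or a log2 difference of 2) and left out each library in turn. For the authors' calls, limits of 4-fold and adjusted p 0.001 were tried. Added after the data were seen were limma-voom on the recovered whole reads and scaling to the total without the 5 globin genes. Permutation tests across genes used 100000 resamples in numpy 2.4.6.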

Results

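RNA was sequenced from endothelial cells of zebrafish embryos at 22 hours post fertilization (hpf). The embryos carried an NF-kB reporter that makes a short-lived green fluorescent protein (NFKB:d2eGFP) and a vascular reporter that makes mCherry from the promoter of kdrl, a VEGF receptor gene (kdrl:mCherry). Trunks were dissected and dissociated, and mCherry-positive cells were separated by flow cytometry into NFKB+ and NFKB- cells, about 7000 cells per sample. There were 3 libraries of each sort, which the labels call biological replicates. The comparison of the sorts bears on the link between NF-kB activity in endothelium and the specification of hematopoietic stem and progenitor cells (HSPCs). NF-kB was not perturbed, so the differences go with reporter fluorescence and are not shown to be effects of NF-kB. The deposited table holds genes that had already passed limits of 2-fold and adjusted p 0.01 in the authors' comparison of these same libraries, and 2471 of its genes were analysed. The reads recovered for them came to 8987344, 8393821 and 15165088 in the NFKB+ libraries and 11129942, 14020673 and 13885062 in the NFKB- libraries. These sums cover the selected genes and are not library depths.

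Vessel and homeobox genes were among the largest excesses in NFKB+ cells, and myeloid genes among the largest in NFKB- cells. Of the 2471 genes, 1347 (54.5%) were higher and 1124 were lower in NFKB+ than in NFKB- cells. A difference of 4-fold or more was seen for 233 higher and 365 lower genes. Among well-measured genes with non-overlapping groups, cx30.3 (NCBI Gene 404725), a connexin of gap junctions, had the largest excess in NFKB+ cells, 10.4-fold. Its level on the log2 scale was 12.12 ± 0.012 (SD, n = 3) in NFKB+ and 8.73 ± 0.18 (SD, n = 3) in NFKB- libraries. E-selectin (sele, Gene 558139), an adhesion receptor of activated endothelium, was 9.55-fold higher, at 13.97 ± 0.51 against 10.71 ± 0.26. The transcription factor gene tfec was 7.63-fold higher and the glycosyltransferase gene b3gnt7 6.50-fold higher. The homeobox genes hoxd10a, hoxa11b, hoxb7a and hoxd9a, which pattern the body axis, were 7.78-, 7.33-, 7.26- and 6.65-fold higher. The remaining leading genes, lyve1b and nrp2b, belong to the venous and lymphatic list. Among the well-measured genes with non-overlapping groups, the lower end was led by lysozyme (lyz, Gene 677744), a myeloid enzyme, at 25.5-fold lower in NFKB+ cells. Its level was 11.84 ± 0.20 against 16.51 ± 0.19. The sterol hydroxylase gene ch25hl2 was 18.4-fold lower, the coagulation factor gene f5 18.1-fold lower, the neutrophil peroxidase gene mpx 15.7-fold lower and the transporter gene abcb9 14.9-fold lower. It also held hsd3b7, fcer1gl, cebp1, myo1f and cd59, which were 14.0-, 13.1-, 12.5-, 12.5- and 11.9-fold lower. The groups did not overlap for 2462 genes (99.6%), against 10% by chance, but the genes had been selected on these libraries.

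Transcripts of kdrl (Gene 796537), whose promoter defined both gates, were 2.30-fold higher in NFKB+ cells, at 15.04 ± 0.041 against 13.84 ± 0.26 (limma adjusted p = 2.07e-07). In the authors' deposited table its log2 fold change was 1.18. Of the 32 annotated members of the list of NF-kB pathway components and feedback genes, 1 was analysed. This was nfkbib (Gene 797834), which encodes an inhibitor of NF-kB, and it was 2.07-fold higher, at 10.43 ± 0.11 against 9.38 ± 0.23. Of 15 inflammatory ligands, receptors and interferon response genes analysed, from a list of 52, 9 were higher and 6 lower. This split did not pass the test against the rest of the table (two-sided Fisher's exact test, adjusted p = 0.854). The chemokine genes cxcl18b and cxcl12b were 5.01- and 4.56-fold higher. The interleukin 6 receptor gene il6r and the chemokine receptor gene cxcr4b were 7.14- and 4.80-fold lower. The globin share of the table's reads, which moved with the sorts, was 7.34% ± 0.588 (SD, n = 3) in NFKB+ and 39.1% ± 2.90 (SD, n = 3) in NFKB- libraries.

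The endothelial list members that were analysed were higher in NFKB+ cells. The 24 pan-endothelial members analysed, of 36 on the list, were higher without exception, with a median log2 difference of 1.54 (Fisher's exact test against the other genes, adjusted p = 2.97e-06). The apelin receptor genes aplnra and aplnrb, which mark angioblasts and veins, were 6.13- and 4.89-fold higher. The vascular genes egfl7 and gpr182 were 4.39- and 4.28-fold higher. The 16 venous and lymphatic members analysed, of 20, were also higher without exception, with a median of 2.08 (adjusted p = 2.31e-04). They included flt4 (Gene 30121), the receptor of VEGF-C, at 6.40-fold, with 15.08 ± 0.068 against 12.40 ± 0.23. The hyaluronan receptor gene lyve1b was 6.96-fold higher, and the neuropilin genes nrp2b and nrp2a were 6.54- and 5.87-fold higher. Of the 35 arterial and Notch members 4 were analysed, too few for the test, and each was higher. The glycosyltransferase genes mfng and lfng, which modify Notch receptors, were 4.80- and 3.63-fold higher, tbx20 was 2.71-fold higher and notch1a 2.14-fold higher. All 12 flow and junction members analysed, of 31, were higher, with a median of 1.45 (adjusted p = 0.00161). Among them, the flow-responsive factor gene klf2a (Gene 117508) was 5.84-fold higher, at 13.09 ± 0.11 against 10.55 ± 0.31. The endothelin gene edn2, the junction regulator gene rasip1 and the endothelin-converting enzyme gene ece1 were 3.59-, 3.46- and 3.28-fold higher. The erythroid and myeloid lists moved the opposite way in the same libraries, with medians of -2.72 and -2.96.

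**Figure D1:**
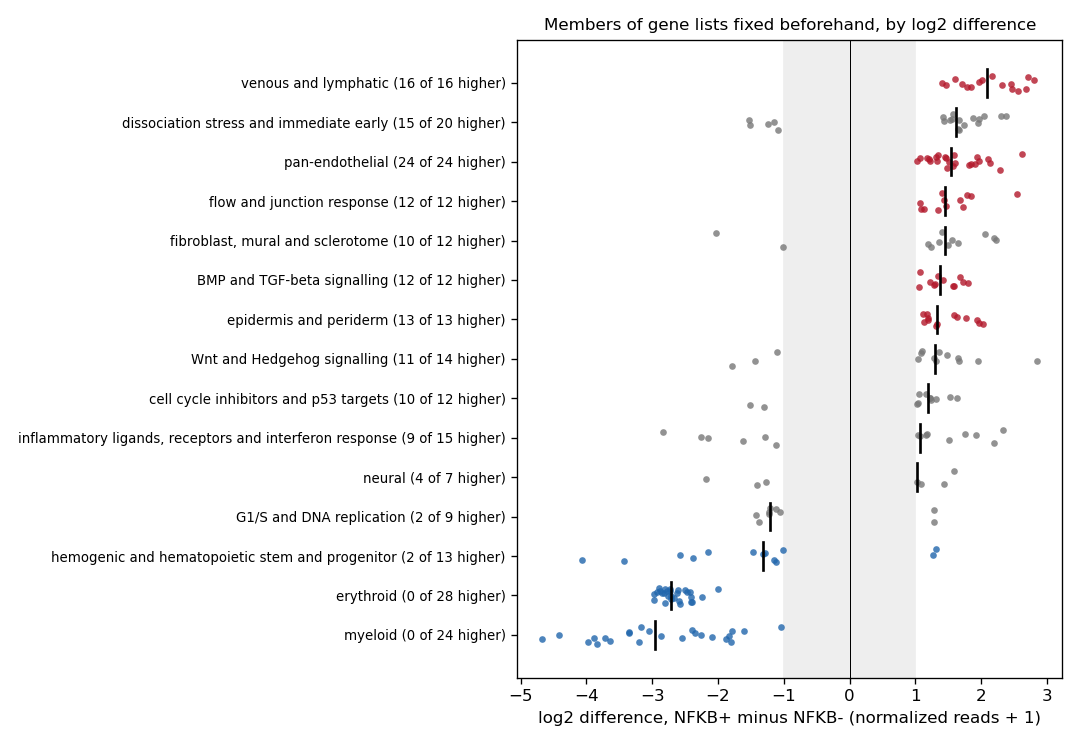
Log2 difference in normalized reads, NFKB+ minus NFKB-, on the horizontal axis for each analysed member (points) of the 15 gene lists with at least 5 members, with the list median as a vertical bar. Red and blue lists held more higher or more lower members than the rest of the table at Fisher adjusted p under 0.05, and grey lists did not; the shaded band is the range under 2-fold that the authors' limit removed. The erythroid points reach down to -2.98 around a median of -2.72, and the 16 venous and lymphatic points between 1.40 and 2.80.

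Blood genes were higher in NFKB- cells. None of the 28 erythroid members analysed, of 37, was higher in NFKB+ cells, and their median log2 difference was -2.72 (Fisher adjusted p = 3.29e-09). The embryonic globin gene hbae1 (Gene 30597) was 7.89-fold lower in NFKB+ cells, at 18.19 ± 0.17 against 21.17 ± 0.20 (SD, n = 3). The globin gene hbbe3 was 7.57-fold lower. Globin reads may be shared between near-identical copies. The nucleotidase gene nt5c2l1 was 7.86-fold lower and klf1, which encodes an erythroid transcription factor, 7.42-fold lower. None of the 24 myeloid members analysed, of 28, was higher either, with a median of -2.96 (adjusted p = 4.03e-08). Besides lyz and mpx, the collagenase gene mmp13a and alox5ap, which is needed for leukotriene synthesis, were 21.3- and 14.8-fold lower. Of the 13 hemogenic and hematopoietic stem and progenitor members analysed, from a list of 33, 11 were lower, with a median of -1.32 (adjusted p = 0.00913). No test separated this fall from that of the erythroid and myeloid members in the same libraries. Transcripts of runx1 (Gene 58126), the transcription factor needed for HSPC emergence, were few, at 6.81 ± 0.49 against 8.09 ± 0.60, which is 2.43-fold lower in NFKB+ cells (limma adjusted p = 0.00164). The progenitor factor gene myb (Gene 30519) was 5.18-fold lower, at 10.88 ± 0.12 against 13.25 ± 0.077. The factor genes runx3, gfi1b and ikzf1 were 16.7-, 5.96- and 4.45-fold lower and the adhesion receptor gene adgrg1 2.77-fold lower. The integrin gene itga2b, at a mean of 40.3 normalized reads, was 10.7-fold lower, but its log2 difference of -3.42 was -2.09 without NFKB+ library 3. The remaining members were lmo4a and fli1a, at 1.27 and 1.31. Of these, fli1a is also on the pan-endothelial list.

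**Figure D2:**
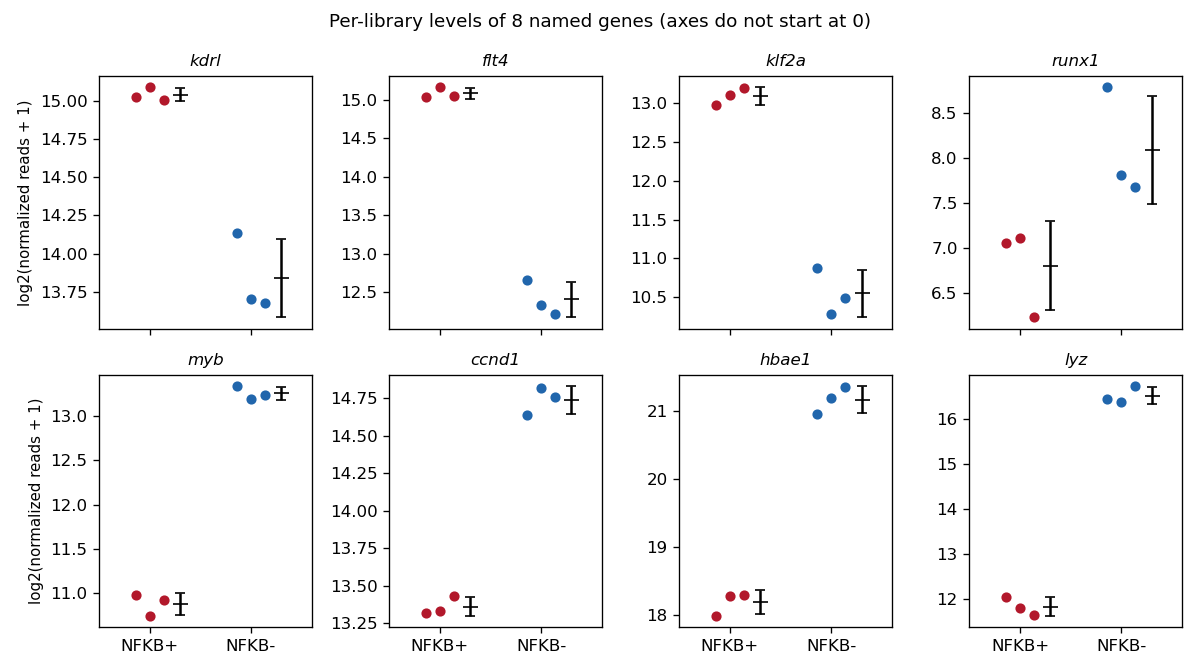
Level of 8 named genes in each library, as log2 of normalized reads plus 1 on the vertical axis, in the NFKB+ (red) and NFKB- (blue) libraries, with the mean and SD (n = 3) in black beside the points. The axes do not start at 0; kdrl, flt4 and klf2a lie higher in the NFKB+ libraries, and runx1, myb, ccnd1, hbae1 and lyz lie higher in the NFKB- libraries, with no overlap between the sorts.

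Cell cycle genes went both ways, and neither list that could be tested passed the test of direction against the rest of the table. With 9 and 12 members, the tests could miss a difference. Of 9 analysed members of the G1/S and DNA replication list, which holds 63, 7 were lower in NFKB+ cells, with a median of -1.20 (Fisher adjusted p = 0.111). The D-type cyclin gene ccnd1 (Gene 30222) was 2.60-fold lower, at 13.36 ± 0.062 against 14.74 ± 0.092. Its relatives ccnd2a and ccnd2b, the members on the other side, were 2.43- and 2.42-fold higher. The thymidylate synthase gene tyms, the replication factor gene mcm10 and the thymidine kinase gene tk1 were 2.67-, 2.34- and 2.33-fold lower. Of 12 cell cycle inhibitors and p53 targets analysed, from a list of 40, 10 were higher, with a median of 1.19 (adjusted p = 0.105). The CDK inhibitor genes cdkn1d and cdkn1ba were 3.11- and 2.87-fold higher, tob1b was 2.49-fold higher and ccng2 2.36-fold higher. On the other side, cdkn3, which encodes a CDK phosphatase, and mdm2, the p53 ubiquitin ligase gene, were 2.84- and 2.48-fold lower. None of the 69 members of the G2/M and mitosis list was among the genes analysed, and neither was any of the 76 listed cytosolic ribosomal protein genes. The mitochondrial list, a rule on names that start with mt, matched only 2 reference symbols and no analysed gene. Mitochondrial transcripts under other names were not checked. Of 3 apoptosis genes analysed, from a list of 27, bcl2l11 and bbc3 were higher, with log2 differences of 1.31 and 1.13, and aifm1 was lower, with one of -1.37. The lower globin share of the NFKB+ libraries went with these differences as well.

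Of the 40 members of the BMP and TGF-beta list 12 were analysed, and these 12 were higher in NFKB+ cells, with a median of 1.38 (Fisher adjusted p = 0.00161). The inhibitory SMAD gene smad7 was 3.46-fold higher, the BMP signal transducer gene smad1 was 3.28-fold higher and its relative smad5 had a log2 difference of 1.68. The ligand gene gdf6a was 2.99-fold higher. In the Wnt and Hedgehog list of 40, 11 of 14 analysed members were higher, which did not pass the test (adjusted p = 0.12). The ligand genes wnt9a and wnt9b were 7.21- and 3.85-fold higher and the nuclear effector gene lef1 3.15-fold higher. The members on the other side were dkk1b, a Wnt antagonist gene, fzd9b and rspo3, with log2 differences of -1.79, -1.44 and -1.11. Of 20 stress and immediate early genes analysed, from a list of 47, 15 were higher (adjusted p = 0.105). The mRNA decay factor genes zfp36l1a and zfp36l1b were 5.19- and 4.92-fold higher, and the AP-1 family genes atf3 and fosl1a 4.12- and 3.91-fold higher. The 5 lower members were hsp90aa1.2, dusp2, hspa4a, egr3 and egr2b. In the same libraries the globin share was 7.34% in NFKB+ against 39.1% in NFKB-, the erythroid and myeloid medians were -2.72 and -2.96, and the pan-endothelial median was 1.54.

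Markers of other trunk tissues did not move as one. All 13 epidermis and periderm members analysed, of 37, were higher in NFKB+ cells, with a median of 1.32 (Fisher adjusted p = 0.0012). The claudin gene cldne, the envoplakin gene evpla and the secreted protein gene agr1 were 4.06-, 3.88- and 3.83-fold higher. The gene foxi3a of ionocytes was 3.39-fold higher, with an SD of 1.08 in NFKB+ and 1.09 in NFKB- libraries on the log2 scale. Of 12 fibroblast, mural and sclerotome genes analysed, from a list of 45, 10 were higher (adjusted p = 0.105). They included foxf2a, fbln1 and mmp2 at 4.68-, 4.56- and 4.17-fold, while pax1a, a sclerotome factor gene, was 4.11-fold lower and zeb2a lay at -1.01. The 7 neural genes analysed, from a list of 50, were split 4 to 3 (adjusted p = 1), with zic2a and isl2a 2.99- and 2.70-fold higher and sox1a and sox19b 4.56- and 2.65-fold lower. Fewer than 5 members were analysed for each of the remaining lists, which were not tested. Of 4 notochord, floor plate and hypochord genes analysed, from a list of 24, matn4 and spon1b were 3.30- and 2.19-fold higher and foxj1b and foxa2 4.12- and 3.28-fold lower. Of 4 pronephros genes analysed, from a list of 25, slc20a1a, osr1 and lhx1a were 5.49-, 4.29- and 2.42-fold lower, and atp1b1a was 3.00-fold higher. The neural crest genes snai2 and tfap2c, from a list of 21, were 2.92- and 2.22-fold higher, and the muscle genes mef2ca and mef2d, from a list of 48, were 2.17- and 2.01-fold higher. These differences, too, went with the globin share of 7.34% against 39.1% and the pan-endothelial median of 1.54.

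In the refit with limma, all 2471 genes passed adjusted p 0.05, the highest being 0.0228, and so did 251 of 251 list places over all genes and adjusted over the list alone. This follows from the authors' selection and is no independent evidence of a difference. The authors' limits apply to both directions alike, but only under the authors' own scaling. A different scaling could change which members pass on each side. The split of a list into higher and lower members therefore depends on that scaling, and genes of a list are not independent replicates. Rescaling by the median ratio over the table moved the median log2 difference by -0.88 and ended the calls of nfkbib, notch1a, mef2d, isl2a, spon1b, foxi3a, tfap2c, ccnd2b, cdkn1d, bcl2l11, bbc3 and wnt9b. For nfkbib the limma adjusted p was then 0.243, the highest of its alternatives, which ranged from 1.48e-06. Rescaling to the same total, a median shift of 0.49, ended the call of runx1, whose adjusted p of 0.0772 was the highest of a range from 1.00e-04. The call of foxi3a also ended with library weights (0.0741) and without NFKB- library 6 (0.0592), within a range from 8.53e-04 to 0.191. Without NFKB+ library 1 its log2 difference was 1.14 instead of 1.76, and without NFKB- library 5 it was 2.29.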

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

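Scaling to the total without globins and limma-voom on recovered reads were chosen after seeing the data. The genes had been selected at 2-fold and adjusted p 0.01 on these libraries, and the scalings shift genes nearly alike by less than that, so the selection largely fixed what follows and it says nothing of stability. No analysed gene changed direction under an alternative run, the 15 tested lists kept their direction and side of the threshold in 165 of 165 comparisons, and counts past the threshold stayed within 1.5 times in 36 of 40. Without 1 library at a time they ranged from 1343 to 1347 higher and 1122 to 1124 lower genes, and limma-voom gave 1347 and 1124. The exceptions follow from the stricter limits themselves. At a log2 difference of 2 or more, 233 genes were higher and 365 lower, and the authors' deposited table held 187 higher and 318 lower genes at 4-fold. The scaling shifted the median log2 difference by 0.49 (same total), -0.11 (total without globins) or -0.88 (median ratios), and the last left 920 higher and 1124 lower genes past the threshold. That scaling assumes a table centred on unchanged genes, which a table filtered at 2-fold does not hold. For named genes, 1644 of 1659 values kept their call and 15 lost it, of which 12 were under median ratios, 1 under the same total, 1 with library weights and 1 without NFKB- library 6. No paired analysis was possible because the columns carry a running number and no replicate number of the labels. The planned edgeR and DESeq2 fits on reads were not run, and limma-voom on the recovered whole reads took their place. Estimated correlation did not apply, since camera was not used. Few reads limit itga2b and runx1, and the selection leaves genes under 2-fold out of reach.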

Other observations

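Families of genes with shared names also differed mostly in 1 direction. These families were picked after the values were seen, from about 20 name patterns browsed, so the adjusted p-values below cover only the 6 kept and understate the search. Of 23 hox genes, 22 were higher in NFKB+ cells, with a median log2 difference of 2.36 (two-sided Fisher's exact test against the rest of the table, adjusted p = 3.18e-05). They included hoxa9b at 3.09 (SE 0.23) and hoxc9a at 2.36 (SE 0.19), and the exception was hoxb1a at -1.66 (SE 0.48). All 17 hox genes with a paralogue number of 9 or more were higher. Of genes matching a pattern of cathepsin, hexosaminidase, legumain and lamp names, which encode lysosomal proteins, 8 of 8 were higher (adjusted p = 0.00953), with the cathepsin gene ctsla at 2.45, also on the venous list (7 of 7 without it, unadjusted p = 0.0182), and the membrane protein gene lamp1 at 2.17. Some lysosomal genes outside the pattern were lower, such as gla at -2.18 and mcoln2 at -2.14. Guidance genes of the semaphorin, plexin, neuropilin and ephrin families were higher in 17 of 19 cases (adjusted p = 0.00226). Here plexin D1 (plxnd1), a vascular semaphorin receptor, lay at 1.69, and the exceptions were plxna4 at -1.48 and sema3bl at -1.27. Of the 19, nrp2a, nrp2b, ephb4a and ephb4b are also on the venous list, and without them 13 of 15 were higher (unadjusted Fisher p = 0.0164). The lysosomal and guidance medians were 1.53 and 1.4, beside a pan-endothelial median of 1.54 and erythroid and myeloid medians of -2.72 and -2.96. No test separated the lysosomal and guidance families from those shifts.

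Genes of ribosome assembly were lower in NFKB+ cells. Of 31 nucleolar and ribosome-assembly genes, 30 were lower, with a median of -1.33 (adjusted p = 4.64e-09). Nucleolin (ncl) lay at -1.25, fibrillarin (fbl), the rRNA methyltransferase, at -1.48 and rrp12 at -1.99. The exception was nol4lb at 1.98, which shares the name pattern. All 14 mitochondrial ribosome genes and all 14 genes with names of translation initiation and elongation factors were lower (adjusted p = 3.11e-05 for each family). The 14 translation names include eif2ak1 and eif4ebp3, which encode inhibitors of initiation, and the other 12 were lower too (unadjusted p = 7.60e-05). Globin, erythroid and myeloid genes were higher in the same NFKB- libraries, and no test separated these families from them. No member of the 69 of the G2/M list was among the genes analysed, against 9 of 63 distinct G1/S members, a contrast noticed in the data. The table does not say why a gene has no row.

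Of the tests below, only that of scaling without globins was set before its result was seen, and the others were chosen afterwards. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 2471 genes past the threshold, and the highest of the others gave 0. With 10 splits no share can be under 0.05, and the genes had been selected on the real split.

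The first pattern is that blood genes were higher in the NFKB- sort. Sequencing depth itself was not tested, since library depth could not be computed, and the compared values were already divided by the size factors. The pattern did not follow the size factors, as all 3 NFKB- size factors lay inside the NFKB+ range. In both NFKB+ libraries at the ends of that range, 52 of 52 blood list members were lower. The selection largely fixed that count, since the groups did not overlap for 99.6% of all analysed genes. Whether globin reads distorted the scaling could not be decided. With scaling to the total without globins, the erythroid median was -2.83 and the myeloid median -3.07. Those totals cover only genes selected on these libraries, and the scaling shifted the median log2 difference by only -0.11. More erythroid cells in the NFKB- sort is a candidate explanation, which a narrow spread of differences cannot decide. The 12 analysed members of the BMP and TGF-beta list, a signalling list, also spanned only 1.06 to 1.79 around a median of 1.38. Of the 28 analysed erythroid members, 27 (96.4%) lay within 0.5 of their median. The most abundant, hbae1, differed by -2.98. The list holds 37 members, and those that did not pass the authors' limits could not enter this share. The gate on kdrl:mCherry would be expected to remove red cells that lack the reporter. Of these members, 0 are on another list, while heme synthesis genes such as urod and fech are used in other cells too. A common ratio for all blood cells stays open. Of 24 myeloid members, 10 lay below the lowest erythroid member, hbae1, by more than 2 of their own standard errors. The error of hbae1 (SE 0.21) was left out, so this count can overstate how many differ. A first test, of spread, also went against a common ratio (permutation p = 1e-05, the smallest that the resamples can give). It was replaced because expression in endothelial cells widens a spread too. The medians differed by -0.24 (permutation p = 0.0605), a test added to the verdict last. Free erythroid RNA in both sorts would compress the erythroid ratio. A biological difference between the sorts, such as blood-forming endothelium with little NF-kB activity, also stays open and untested.

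The second pattern is that endothelial genes were higher in NFKB+ cells. If a share of blood cells diluted all endothelial transcripts alike, venous and pan-endothelial members would differ by a like amount. Their medians were 2.08 and 1.54 (permutation p = 0.00307 across genes, which are not independent replicates). The test was repeated against 16 pan-endothelial members, leaving out 8 counted here as shared with blood cells (fli1a, fli1b, erg, etv2, ets1, hhex, yrk and pecam1). This restriction was added after that result and was not made in the venous list, and the permutation p was 0.0651. Both medians cover only members past the 2-fold limit, 16 of 20 venous and 24 of 36 pan-endothelial, so members that differed less are missing. Dilution and a more venous makeup of the NFKB+ cells therefore cannot be told apart for these genes. The medians are of selected members, and the second comparison leaves the difference unresolved.

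The third pattern is the hox genes. Their median exceeded the pan-endothelial one by 0.82 (permutation p = 2.20e-04, and 0.00653 against the narrower 16 members), but the family was picked for its values, so these p-values decide nothing, and dilution by blood cells alone cannot be told apart from a further difference. A more posterior origin of the NFKB+ cells within the dissected trunk is a candidate explanation. Across the 23 genes, the log2 difference had a Spearman rho of 0.331 with paralogue number (permutation p = 0.122) and a Pearson r of 0.635 (p = 0.00147). Without hoxb1a and either of the genes tied at paralogue number 3, r was 0.429 (hoxd3a left out) or 0.242 (hoxc3a left out), with rho 0.206 or 0.125, and without hoxb1a alone r was 0.390, so the relation rests largely on hoxb1a and a posterior origin cannot be told apart from a hox program of certain endothelial cells.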
